A study of Rattus norvegicus with 20 samples.

How the data were processed

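Total RNA of rat lung was measured on 20 expression arrays, and the deposited table of processed values was analysed. It held 1 value for each of 1185 probes in each array, 702 with the prefix R and 483 with the prefix RG. The platform, scanner, background correction, normalization method and base of the logarithm are not given in the sources used here. The deposited values have 2 decimals, run from -1.95 to 9.71 and are centred: array medians lay between -0.01 and 0. They look log-scaled from their distribution, but whether the base is 2 or e could not be settled. The authors' values were not scaled to a common spread, since the interquartile range of the arrays ran from 0.42 to 1.75, a ratio of 4.17. Signal over background is not given, so how many probes were above background is unknown.

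Groups were taken from the array titles. The running numbers in the titles are unique, so they pair no arrays between groups. NL (5 arrays) served as the reference, and the Normal Day 0 array, a single sample, was left out of the tests and added to NL only as an alternative. The comparisons, tests, threshold, filter and most alternatives were chosen before the data were examined. The plan was written for log2 values; the deposited values were used as they are because they were already on a log-like scale and centred. No floor was therefore applied, and the planned floors were run as alternatives at the 20th and 2nd percentile, -0.42 and -1.27.

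Probes above the 25th percentile of all values (-0.32) in at least 3 of the 19 arrays were tested, 1179 in all. One linear model over 6 groups with 13 residual degrees of freedom was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that groups of 2 to 5 arrays shared an estimate of the spread. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the probes tested in each comparison, with a threshold of 0.05. Each day and T were compared with NL, and T also with Day 35 and with the mean of the 4 days. A moderated F-test compared the 4 days with NL, and another compared the days with each other. No batch is given in the labels, so no covariate was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

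The rule for named items was the 10 probes per direction with the largest difference, among called probes whose array ranges did not overlap and that match exactly 1 gene symbol, and the 10 with the smallest p in each F-test. No table used here pairs the probes with genes, so no probe met the symbol condition. At most 2 identifiers per direction are therefore given from the rule. Where a count was 5 or fewer the remaining probes are named too, and these, the brightest probes and the probes followed across groups were chosen after their values were seen. The 26 gene lists fixed in advance, their camera tests and the test of gene means were not run for the same reason.

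Similarity of the T and Day 35 differences was set against 1000 simulated sets of unchanged groups, built from deviations of arrays from their group means and sharing their controls. Calls, and the overlap of the probes ranked first, were counted in 100 sets of unchanged groups; the ranked lists were added after seeing the data. The fit was tested on simulated data with 200 changed probes in 20 draws. Where fewer probes change, the Benjamini-Hochberg adjustment is stricter and a smaller share would be recovered. The shares below therefore do not carry over to comparisons with few calls. For Day 35 against NL, 64.0% of probes changed by 1 unit and 93.6% of those changed by 2 units were recovered among 1179 independent probes. With whole residual arrays resampled, which keeps the correlation between probes, 58.1% and 92.6% were recovered with a mean of 22.1 false calls. For T against NL the latter values were 58.8% and 93.5%, with 10.0 false calls. Independent probes gave a mean of 7.35 false calls for Day 35 and 6.45 for T. An adjusted p under 0.05 may therefore understate the false calls where probes correlate.

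Alternatives covered quantile normalization, median centring, floors, filters, the Normal Day 0 array as a control, fits to only the groups compared, trended and robust variances, array weights and leaving out each array. Added after seeing the data were scaling to a common interquartile range, the cluster of 6 arrays as a block, fits without NL arrays 4 to 6 with and without that block, a fit without Day 21 array 9, and, for the calls against NL, the other 9 sets of 3 NL arrays left out.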

Results

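Gene expression was measured on arrays of total RNA from whole rat lung, in a series on neointimal vascular proliferation (growth of cells inside the vessel wall) and pulmonary hypertension followed over time. The 20 arrays carried 1185 probes and fell into 7 labelled groups. NL had 5 arrays (numbered 2 to 6), Day 14 had 2, Day 21, Day 28, Day 35 and T had 3 each, and a single array was titled Normal Day 0. The labels do not expand NL or T and do not give the day of T. They also do not say whether arrays came from separate animals, so p-values measure the spread between these samples, which may be technical. The files do not pair probes with genes, so probes are given by their identifiers and no gene group could be described. The number of arrays limits the precision. All values are on the deposited scale, which looked logarithmic but has no stated base, so differences are given in its units and not as folds.

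Taken over all groups, pairs of arrays that shared a group did not correlate better than other pairs. The median Spearman correlation over all probes was 0.780 in the 23 pairs of arrays that shared a group and 0.801 in the 167 pairs that did not. By group the median was 0.765 in the 10 NL pairs, 0.737 in the Day 14 pair, 0.751 at Day 21, 0.813 at Day 28, 0.861 at Day 35 and 0.864 in T. Without NL and Normal Day 0 it was 0.813 in 13 pairs that shared a group and 0.842 in 78 that did not. The closest pair was Day 21 array 11 with T array 19, at 0.958. Average-linkage clustering cut at 4 clusters put NL array 2, all Day 35 arrays and the Normal Day 0 array in a cluster of 11. A cluster of 6 held NL array 3, Day 14 array 8, Day 21 array 11, Day 28 arrays 12 and 14 and T array 19. NL array 4 stood alone, and NL arrays 5 and 6 formed the fourth cluster. The spread of values also differed between arrays: the interquartile range ran from 0.42 in NL arrays 5 and 6 to 1.75 in Day 21 array 11. It ran from 1.45 to 1.75 in the cluster of 6 and from 0.49 to 1.54 in the cluster of 11. Probes R371 and R372 were the brightest, with means of 8.20 ± 1.12 and 7.51 ± 0.88 (SD, n = 20 arrays). No array held values identical to another.

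**Figure D1:**
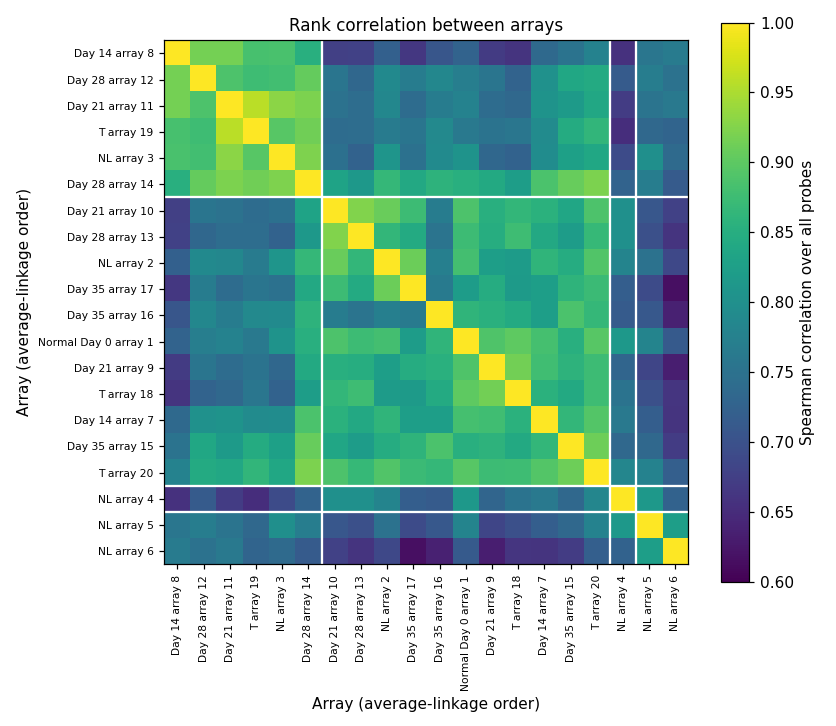
Spearman correlation between each pair of the 20 arrays over all 1185 probes (colour scale, no unit), with arrays on both axes in average-linkage order and white lines between the 4 clusters. Arrays of one labelled group lie in different clusters for every replicated group except Day 35, and the highest correlation is 0.958.

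The first question was which probes changed over the labelled days. Probe R272 differed from NL over the labelled days. Its value was -0.07 ± 0.25 (SD, n = 5) in NL, 0.82 ± 0.55 (n = 2) at Day 14, 1.94 ± 0.90 (n = 3) at Day 21, 1.60 ± 0.53 (n = 3) at Day 28 and 2.85 ± 0.48 (n = 3) at Day 35. The Normal Day 0 array, which was not part of the test, read 1.69 for this probe. Probe R525 read 0.08 ± 0.30 in NL and 1.84 ± 0.29 at Day 35, and probe R511 read -0.15 ± 0.19 and 2.14 ± 0.07. These 3 probes passed the limma moderated F-test of the 4 days against NL, with adjusted p of 0.00712 for R272 and R525 and 0.0250 for R511. In all, 56 probes had an unadjusted p under 0.05, where 58.95 of the 1179 tested are expected by chance. The count was 0 without NL arrays 4 to 6, while the Day 35 differences of the 3 probes were 2.72 for R272, 1.52 for R525 and 2.41 for R511. Of the 9 other ways to leave out 3 NL arrays, 5 also gave 0 (range 0 to 29). Those that left out NL arrays 2 and 3, and so kept most of NL arrays 4 to 6, gave 11 to 29, and the rest gave 0 or 1. The count was also 0 with all arrays scaled to a common interquartile range, where the Day 35 differences of the 3 probes were 3.00, 1.67 and 2.21. It was 1 after quantile normalization, 6 with the Normal Day 0 array added to NL, 10 with trended and robust variances, 6 without NL array 2, 18 without Day 14 array 8, 6 without Day 21 array 9, 1 without Day 35 array 15 and 6 without Day 35 array 17.

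At Day 14, 0 probes were called against NL by limma, with a smallest adjusted p of 0.0879. Unadjusted p was under 0.05 for 59 probes, against 58.95 expected. Without Day 14 array 8, which leaves 1 array assumed to vary like the other groups, 14 probes were called. With values floored at the 20th percentile, 1 probe was called.

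At Day 21, R272 was the 1 probe called. It was 2.02 higher than in NL (SE 0.37, limma adjusted p = 0.0496), and all 3 Day 21 arrays lay above all 5 NL arrays. For R706 and R098, Day 21 array 9 read 4.73 and 4.11, while the other Day 21 arrays read 0.42 and 1.05 for R706 and 0.32 and 0.53 for R098. Unadjusted p was under 0.05 for 28 probes, fewer than the 58.95 expected by chance. The call of R272 stood at the edge of the threshold and was lost in 23 of 34 alternatives, including the fit without Day 21 array 9 and, counting that fit again, 14 of the 19 fits that left out 1 array. Over the alternatives its adjusted p ran from 0.000208 to 1. The lowest value came from array weights, which did not converge, and the next lowest limma value was 0.0160, without Day 21 array 10.

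At Day 28, 0 probes were called by limma, with a smallest adjusted p of 0.346. Unadjusted p was under 0.05 for 58 probes, against 58.95 expected. R272 stood 1.67 above NL (SE 0.37) without passing the adjusted threshold. A fit to the NL and Day 28 arrays alone called 1 probe, and leaving out NL array 2 also gave 1.

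At Day 35, 14 probes were higher than in NL and 0 were lower. Their differences ran from 1.32 to 4.42, with a median of 2.32. R706 had the largest difference: it read 0.04 ± 0.22 (SD, n = 5) in NL and 4.46 ± 0.49 (n = 3) at Day 35, a difference of 4.42 (SE 0.71, limma adjusted p = 0.00343). R098 read -0.01 ± 0.21 in NL and 3.33 ± 0.63 at Day 35, a difference of 3.35 (SE 0.61, adjusted p = 0.00576). R272 was 2.92 higher (adjusted p = 0.000391), R511 was 2.29 higher (adjusted p = 0.00180) and R525 was 1.76 higher (adjusted p = 0.000391). For these 5 probes every Day 35 array lay above every NL array. Unadjusted p was under 0.05 for 120 probes, 88 higher and 32 lower, against 58.95 expected. The ranges of the groups did not overlap for 84 probes, or 7.12%, where chance gives 3.57%.

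The same 14 probes were selected at Day 35 against the NL arrays, so their values there are the largest by construction, and low NL values favour positive differences in the other groups too. Their median difference from NL was 0.36 at Day 14, 0.51 at Day 21, 0.70 at Day 28 and 1.33 in T. All 14 means lay above NL in each of these groups, but so did all 14 of the probes ranked first in 24 to 33 of 100 simulated sets of unchanged groups, depending on the group. In those sets the median difference of such probes reached the observed value in 28 draws for Day 14, 11 for Day 21, 1 for Day 28 and 0 for T. The simulated probes were not matched to the 14 in spread or in Day 35 difference, so these counts do not decide whether the 14 were raised in those groups. The limma F-test of differences among the days called 0 probes, with a smallest adjusted p of 0.0647 and 41 probes at an unadjusted p under 0.05, so no probe was shown to differ between days. That count rose to 10 without Day 14 array 8, 4 without Day 21 array 9, 3 without Day 35 array 17, and 1 without T array 18 or T array 19.

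The Day 35 count changed with the number of NL arrays and with which ones were kept. Without NL arrays 4 to 6, 0 probes passed, and the other 9 ways to leave out 3 NL arrays gave 0 to 100. Sets of 3 left out that included NL array 2 gave 5 to 100 calls, and sets without it gave 0 to 3. Sets that left out NL arrays 2 and 3, and so kept 2 of NL arrays 4 to 6, gave 33 to 100, and all other sets gave 0 to 10. Without NL arrays 4 to 6 the median difference of the 14 probes was 1.95 in place of 2.32, and its median SE was 0.49 in place of 0.38. Quantile normalization gave 32 probes, 23 of them higher, and all 14 were among them. The count was 43 without NL array 2, 5 without Day 35 array 15, 9 without Day 35 array 16 and 9 with a common interquartile range. The last 9 included 7 of the 14 and not R706 (adjusted p = 0.153, difference 4.33) or R098 (adjusted p = 0.239, difference 3.23); over all alternatives their adjusted p ran from 1.07e-05 to 0.153 and from 4.67e-06 to 0.239.

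**Figure D2:**
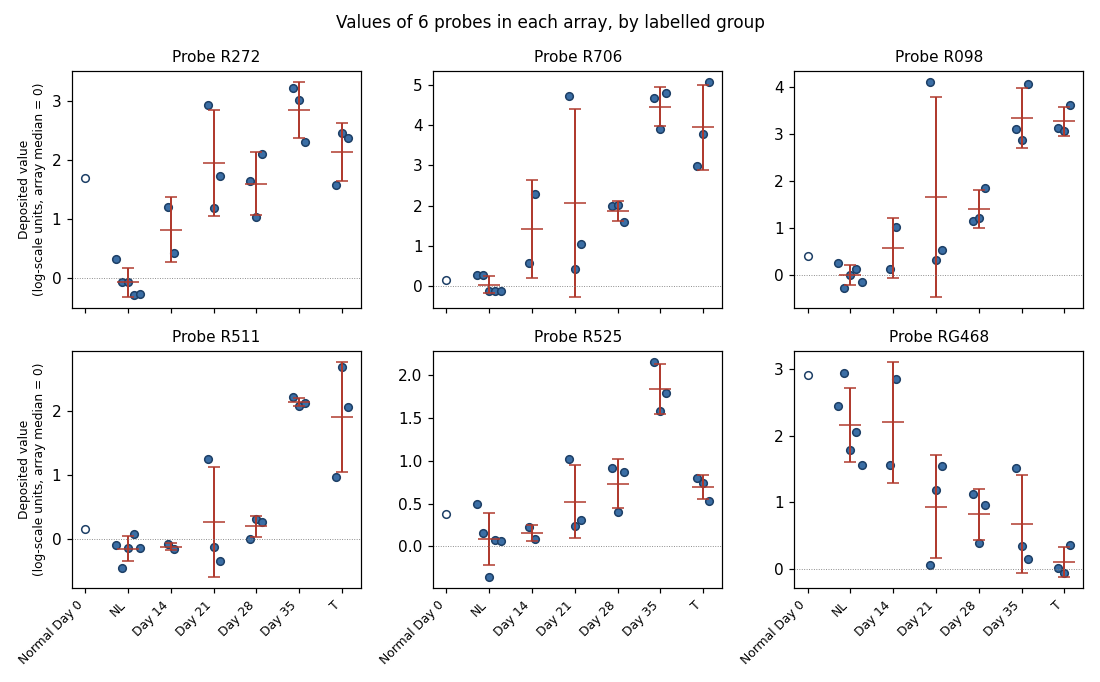
Deposited values (vertical axis, log-scale units with each array's median at 0) of 6 probes in the 20 arrays by labelled group (horizontal axis); points are arrays, the open point is the Normal Day 0 array, and red bars are the mean ± SD of groups with more than 1 array. R706 lies between 3.9 and 4.8 in the Day 35 arrays and at or below 0.28 in the NL arrays, and RG468 lies at or below 0.36 in T and at or above 1.56 in NL.

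**Figure D3:**
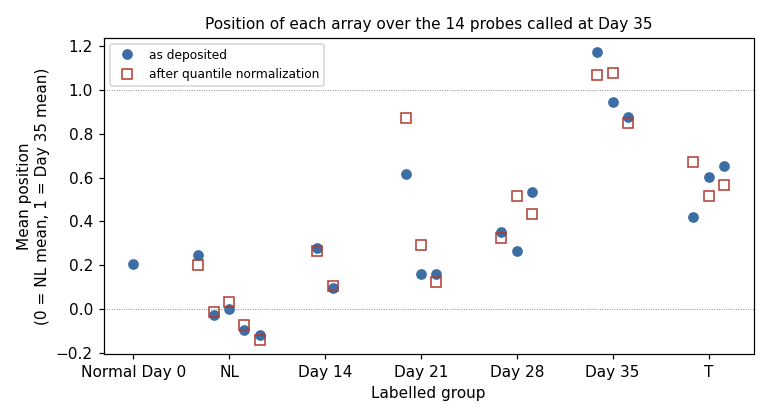
Mean position of each array over the 14 probes called at Day 35 (vertical axis, 0 at the NL mean and 1 at the Day 35 mean, no unit) by labelled group (horizontal axis), for deposited values (filled points) and after quantile normalization (open squares; the Normal Day 0 array was not normalized). As deposited, Day 21 array 9 stands at 0.616 and the other Day 21 arrays at 0.161, and the T arrays stand between 0.419 and 0.652.

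In T, 4 probes were higher than in NL and 1 was lower. R706 read 3.95 ± 1.06 (SD, n = 3), a difference of 3.91 (SE 0.71, limma adjusted p = 0.0162), and R098 read 3.26 ± 0.31, a difference of 3.27 (SE 0.61, adjusted p = 0.0162). R272 was 2.21 higher and R511 was 2.05 higher, both with adjusted p of 0.00989. With the Normal Day 0 array added to NL, the difference of R272 was 1.91 and was no longer called (adjusted p = 0.0928; range over all alternatives 0.000651 to 0.221). RG468 was lower: it read 2.16 ± 0.55 in NL and 0.10 ± 0.23 in T, a difference of -2.06 (SE 0.41, adjusted p = 0.0271). For RG468 the Normal Day 0 array read 2.92, and the difference from NL at Day 35 was -1.49 (adjusted p = 0.120). Every T array lay outside the range of the NL arrays for all 5 probes. Unadjusted p was under 0.05 for 73 probes, against 58.95 expected. The count was 0 without T array 19, 0 without T array 20, 0 without NL arrays 4 to 6 and 0 with a common interquartile range. Of the 9 other ways to leave out 3 NL arrays, 5 also gave 0 (range 0 to 54). Those that left out NL arrays 2 and 3, and so kept most of NL arrays 4 to 6, gave 9 to 54, and the rest gave 0 or 1. Without NL arrays 4 to 6 the differences of the 4 higher probes ran from 2.00 to 3.67 and that of RG468 was -2.60; with a common interquartile range they ran from 1.91 to 4.04 and it was -3.12. The count was 3 without T array 18, 11 without NL array 2 and 11 with values floored at the 20th percentile.

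Against Day 35, 0 probes were called in T by limma, with a smallest adjusted p of 0.354. Unadjusted p was under 0.05 for 19 probes, fewer than the 58.95 expected. The 14 probes called at Day 35 had a median difference of -0.93 in T minus Day 35, and 7 of them had an unadjusted p under 0.05. Because they were chosen for being high at Day 35, a lower value in any other group is favoured by the choice. R706 differed by -0.51 (SE 0.80) and R098 by -0.07 (SE 0.68). Differences of about 1 unit in either direction, and a larger fall for R706, were therefore not excluded. Without Day 35 array 17, 3 probes were called. Against the equally weighted mean of the 4 days, 0 probes were called in T, with a smallest adjusted p of 0.791 and 16 probes at an unadjusted p under 0.05. That count was 2 without Day 21 array 9 and 1 without T array 18.

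All 4 probes called higher in T were also called higher at Day 35, where independent lists would share 0.0475 probes. Both comparisons use the NL arrays, which raises such overlap. In 100 simulated sets of unchanged groups against shared controls, the 14 probes ranked first as higher at Day 35 and the 4 ranked first as higher in T shared 0.49 on average and 3 at most. Across the 1179 probes, which are not independent, the differences of T and of Day 35 from NL correlated with r = 0.764. Unchanged groups gave a mean r of 0.341, and the central 95% of their values ran from -0.480 to 0.863, so the observed r lay inside the range of unchanged groups. The covariance was 0.193 against a simulated mean of 0.0559, a difference of 0.137, and the upper end of the central 95% of simulated covariances was 0.255. With NL split into 2 and 3 arrays, so that the comparisons shared no NL array, r averaged 0.454 over 20 values and ran from 0.0189 to 0.763, and the covariance averaged 0.132. The sign of the difference was shared by 73.2% of probes, against 61.9% in unchanged groups.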

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

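Of the tests in this part, the splits of the arrays were planned; the tests on NL arrays 4 to 6, on the spread of values, on similarity by group and on Day 21 array 9 were chosen only after the result was seen, as were the readings of the NL, spread, group and Day 21 tests where their values disagreed.

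The Normal Day 0 array, not used in the comparisons, read above every NL array for 3 of the 6 probes named: 1.69 for R272, where the highest NL array read 0.33, 0.15 for R511 (highest NL 0.07) and 0.40 for R098 (highest NL 0.25). For R272 it lay among the Day 28 arrays, which ran from 1.04 to 2.10. All of the 6 probes but RG468 had been chosen as higher than NL. Low NL values, and so a reading above NL in another array, are favoured by that choice. Tests for a single outlying array, run on 7 measures (the 6 named probes and the interquartile range) in NL, the 1 group of at least 4 arrays, found 0 where chance gives about 1 in 20.

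The first pattern is the set of 14 probes called higher at Day 35. A two-group limma fit called 11 probes for the real groups, and 3 of the 56 splits of the 8 arrays gave as many, the real one included, so chance is not excluded; the highest other split, NL arrays 4 to 6 against the rest, called 75, several times the real count, which points to a structure of the samples. Unequal spread of the arrays stays open: the median difference of the 14 probes was 2.20 after quantile normalization, with all 14 called, and 2.18 with a common interquartile range, but there the median SE rose from 0.38 to 0.57 and 7 of the 14, R706 and R098 among them, lost their calls. Without NL arrays 4 to 6, 0 calls were left. Of the 9 other sets of 3 NL arrays left out, 2 also gave 0, and both of these lacked 2 of arrays 4 to 6. Sets that left out NL arrays 2 and 3, and so kept 2 of arrays 4 to 6, gave 33 to 100 calls. Sets that left out 2 of arrays 4 to 6 gave 5 to 10 calls without NL array 2 and 0 to 3 with it. The count thus went with how many of arrays 4 to 6 were kept, and also with NL array 2. NL arrays 4 to 6 as the source also stay open. Against that source, the median difference from NL arrays 2 and 3 was 1.95 of 2.32, all 14 kept an unadjusted p under 0.05, and all 14 were higher than NL array 2 (median 1.58) and than the Normal Day 0 array (median 1.70), but the NL arrays had served to choose the probes and the Normal Day 0 array is 1 sample; a change with the labelled day stays open.

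The second pattern is that arrays correlated across groups, and whether the labelled groups set any of their similarity stays open: over the 19 arrays without Normal Day 0, the median Spearman correlation was 0.780 in 23 pairs of one group and 0.791 in 148 pairs of different groups, a difference of -0.0102 (one-sided permutation p = 0.604), though the medians within Day 35 (0.861) and T (0.864) were higher. Spearman correlation uses ranks, which rescaling a whole array leaves unchanged, so unequal scale alone cannot set these correlations. Whether unequal spread underlies the variation of the values themselves stays open. After quantile normalization the first component still carried 39.5% of the within-group variation (46.5% as deposited), where 100 shuffles reached at most 13.1%. That component remained related to the deposited spread. As deposited, the size of Pearson's r of the component over 19 arrays was 0.909 with the interquartile range and 0.963 with that range less its group mean (rho 0.904 and 0.943; permutation p = 1e-05 for each, the smallest possible, adjusted over 4 relations 2e-05; r 0.927 and 0.945 without the 2 arrays farthest from the median of each measure, 0.924 and 0.978 within 10 arrays of the largest cluster, 0.430 and 0.920 within the cluster of 6). After normalization it was 0.513 and 0.543 (rho 0.525 and 0.521; permutation p = 0.0262 and 0.0176 for r, 0.0227 and 0.0241 for rho, adjusted 0.0262 and 0.0235, 0.0241 for both rho; r 0.753 and 0.354 without the 2 arrays farthest out on each measure, 0.446 and 0.416 within the largest cluster, 0.127 and 0.348 within the cluster of 6), so the relation with the range less its group mean rested in part on 2 arrays. A batch of handling or hybridization may underlie the clusters, but the labels give none and it was not tested, nor was any biological explanation other than the labelled groups.

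The third pattern is Day 21 array 9, which lay nearer Day 35 than the other Day 21 arrays over the 14 probes. On a scale from the NL mean (0) to the Day 35 mean (1) it stood at 0.616, and the other Day 21 arrays both stood at 0.161. Unequal spread is argued against, since its lead over the higher of the other Day 21 arrays was 0.581 after quantile normalization and 0.832 with a common interquartile range (0.455 as deposited). The scalings disagree on whether array 9 is a Day 35 or a T sample under a Day 21 label. Neither can be told apart from a Day 21 sample that differed from its group. As deposited it lay below the lowest Day 35 array (0.879) by more than the Day 35 SD (0.155), and inside the T range of 0.419 to 0.652. After quantile normalization it stood at 0.872, above the lowest Day 35 array (0.850) and the highest T array (0.670). With a common interquartile range it stood at 1.22, also above the lowest Day 35 array (0.901). Its median Spearman correlation was 0.0202 higher with T (0.915, 0.873 and 0.752) than with Day 35 arrays (0.847 to 0.859). Its correlation was 0.890 with Normal Day 0 and 0.877 with Day 14 array 7. In array 9, 10 of the 14 probes lay below every Day 35 array as deposited and 7 after quantile normalization. The 14 probes were chosen for being high in these same Day 35 arrays, so a lower position in any other array is favoured by the choice.

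For T against NL the real groups gave 5 probes, 4 of 56 splits gave as many, and the highest other, NL array 3 with T arrays 19 and 20 against the rest, gave 280, so chance is not excluded. For Day 28 against NL the real groups gave 1, 6 of 56 splits gave as many, and the highest other gave 396, so chance is not excluded there either. For Day 21 against NL the real groups gave 0 in the two-group fit, so that all 56 splits had to give as many and the count decides nothing; the highest other gave 277. Splits that called many more probes than the real one point to a structure of the samples. In 100 simulated sets of unchanged groups in the fit over all groups, 1 gave as many as 14 calls for Day 35, and 3 each gave as many as 5 for T, 1 for Day 21 and 3 over the time course, with highest counts of 223, 156, 226 and 288. T against Day 35 allows 10 splits, too few for a share under 0.05: the real groups and the highest other both gave 0, and all 10 gave as many.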

How the results depend on the processing

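The settings below were fixed in advance, except scaling to a common interquartile range, the cluster of 6 arrays as a block, and the fits without NL arrays 4 to 6 or Day 21 array 9, chosen only after. Of 374 alternative values for the 11 named differences, 309 kept their call, 65 lost it and 0 reversed; the fit without Day 21 array 9 is counted again among the fits that left out 1 array. Day 35 against NL (14 probes) gave 32 after quantile normalization, 9 with a common interquartile range, 22 with the cluster block (all 14 among them) and 0 without NL arrays 4 to 6, with or without the block. T against NL (5) gave 11 with the 20th percentile floor, 9 with the block, and 0 with a common interquartile range or without NL arrays 4 to 6, with or without the block. The time course (3) gave 1 after quantile normalization, 6 with the Normal Day 0 array in NL, 10 with trended and robust variances, 6 without Day 21 array 9, and 0 with a common interquartile range or without NL arrays 4 to 6, with or without the block. Day 21 (1) gave 0 with the 20th percentile floor, the Normal Day 0 array in NL, only the groups compared, trended and robust variances, a common interquartile range, the block, without NL arrays 4 to 6 (with or without the block) and without Day 21 array 9. Day 14 (0) gave 1 with the 20th percentile floor, and Day 28 (0) gave 1 with only the groups compared. Differences among the days (0) gave 1 with the 20th percentile floor, 2 with the Normal Day 0 array in NL, 1 with trended and robust variances and 4 without Day 21 array 9; T against the mean of the days (0) gave 2 without Day 21 array 9. Array weights did not converge and put most weight on NL arrays 5 (8.55) and 6 (5.74), so their counts are unreliable: 672 over the time course, 177 among the days, 170 at Day 21, 625 at Day 28, 564 at Day 35 and 293 in T. Leaving out 1 array at a time gave 0 to 14 at Day 14, 0 to 2 at Day 21, 0 to 1 at Day 28, 5 to 43 at Day 35, 0 to 11 for T against NL, 0 to 3 for T against Day 35, 0 to 2 for T against the mean of the days, 1 to 18 over the time course and 0 to 10 among the days. The correlation of T and Day 35 differences ran from 0.454 to 0.879 over all alternatives (0.658 to 0.825 leaving out 1 array), and moved by less than the SD of simulated unchanged groups, 0.372. The fits without NL arrays 4 to 6 leave 2 NL arrays, which widens the errors; the cause of the other changes was not tested. Median centring moved almost nothing because the medians were already near 0, and the filters and the lower floor kept counts within 1.5 times. No paired analysis was possible because the array numbers are unique. Gene means and gene lists were not run because probes carry no gene names. Signal over background is unknown, so the limit it sets is too.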

Other observations

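The median correlation of consecutive probe numbers was planned as a test; the count of strongly correlated pairs was chosen only after its value was seen.

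Probes with consecutive numbers could share a gene or a gene family. After removal of group means and 3 components from quantile-normalized values, the median correlation over arrays of 1098 consecutive pairs was 0.00925 (one-sided permutation p = 0.204), so consecutive pairs in general did not vary together. However, 15 pairs correlated above 0.8, where 1000 shuffles of the probes gave 4.93 on average and 13 at most. Whether these pairs measure related transcripts is a hypothesis that needs the probe-to-gene table to test, and no other source of their correlation was tested. The highest pair, R127 and R128, reached 0.888.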
